A study of Mus musculus with 7 samples.

How the data were processed

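Bulk RNA sequencing was performed on whole kidney tissue of 7 adult male mice on a mixed 129S1/Sv and C57BL/6 background, 3 labelled wild type and 4 labelled knockout for cadherin-11. Per the labels' protocols, each mouse lost a kidney by uninephrectomy, received angiotensin II from an osmotic pump at 800 ng/kg/min, and was killed 4 weeks after surgery. Total RNA was extracted with a Trizol and column procedure and directional libraries were made with a NEBNext Ultra II kit, per the labels' protocols. Groups came from the genotype given in the labels. Replicate numbers within a group follow the order of deposit and only name libraries, so no library of a group is paired with a library of the other.

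A count table and a table of normalized values were deposited, with a column for each library. The authors' expected counts are estimated reads per gene, deposited as whole numbers, with column names typical of a transcript quantifier. The submitters' processing notes name DRAGEN, DESeq2 and the mouse build mm10, without versions, and the annotation release, strand setting and filters were not given in the sources used here. The deposited normalized values (a signal without a fixed total) equal the counts multiplied by gene-specific factors. These factors differ between genes within a library, unlike a single size factor per library. What sets these factors was not given in the sources used here, and they can shift the normalized values of a gene between libraries without a change in its counts. The main tests therefore used the deposited expected counts, and the normalized values entered only as alternatives. No further rounding was needed.

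Gene symbols and positions were taken from GENCODE release M21, on the same mouse assembly as mm10. Of 42256 identifiers, 42170 matched a symbol, and 25635 had at least 1 count. Genes with near-identical copies, shared exons or antisense partners are uncertain, since the way reads were divided among them was not given. All 21 pairs of libraries were compared by a chi-square test per gene. The median value over genes (1 degree of freedom) ranged from 2.70 to 12.86, so no pair agreed within sampling noise and all 7 libraries were counted as separate samples.

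Total counts ranged from 72087906 to 84786351 per library. Genes were filtered with filterByExpr on the groups, which left 17964, and library sizes were scaled by TMM. The main test was edgeR's quasi-likelihood test with robust estimation (edgeR 4.0.16, R 4.3.3), 2-sided, without covariates, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Depth-scaled counts (CPM) were computed on TMM-scaled library sizes. The common dispersion was 0.0231, a biological coefficient of variation of 15.2%. The edgeR step was tried on simulated counts of 4 against 3 libraries over 17964 genes. It recovered 35.8% of 67 genes with a log2 change of 0.5, 80.6% of 67 with 1 and 95.5% of 66 with 2. Of its calls, 7.2% were unchanged genes. The changed genes were few and drawn from those with higher counts. In the data 29.7% of tested genes were called, so these rates are not the power of the comparison.

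All 34 fixed gene lists were examined, and those with enough members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 32 lists with at least 5 tested members. The same lists were tested with a correlation estimated from the data and with fry, and members were counted both over all genes and adjusted over the list alone. Genes within 10 Mb of Cdh11 were compared with all other genes by a 2-sided Fisher's exact test. The lists, tests, alternatives and naming rule were fixed before the data were examined. Named genes were Cdh11, the 12 largest rises and the 12 largest falls among called genes with a mean of at least 1 CPM and no overlap between groups, up to 4 called members of each list by adjusted p (otherwise the 2 most abundant), and the 4 called genes near Cdh11 with the smallest adjusted p. Predicted gene models were named only among the 3 largest changes of a direction. Some genes that meet this rule are not reported here.

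Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, relative log expression and upper-quartile scaling, no filter, a mean of at least 1 CPM, no robust estimation, 1 surrogate variable (sva 3.50.0), limma-trend on log2 of the deposited normalized value plus 1, other thresholds and windows, and the omission of each library. A fit with the deposited gene-specific factors as offsets and a fit on protein-coding genes only were added after seeing the data. Summaries and the permutation test used Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1, and Fisher's exact test used R.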

Results

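RNA from the kidneys of 7 adult male mice was sequenced 4 weeks after uninephrectomy and the start of angiotensin II infusion. Together these are a hypertensive model of kidney injury. No library came from a mouse without them, so a difference present before injury cannot be told from a different response to injury. The question was which transcripts differ in injured kidneys between 3 mice labelled wild type and 4 labelled knockout for Cdh11, which encodes cadherin-11, a cell adhesion molecule of mesenchymal cells. Total counts were 72117499, 78809730 and 81812964 in wild-type-labelled replicates 1 to 3 and 82608991, 72087906, 84786351 and 81375871 in knockout-labelled replicates 1 to 4. Mitochondrial ribosomal RNA took 16.1% ± 2.40 (SD, n = 3) of the counts in the wild-type-labelled group and 11.8% ± 1.38 (SD, n = 4) in the other. Adjusted p-values of genes come from edgeR's quasi-likelihood test and those of lists from camera, both with Benjamini-Hochberg adjustment.

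Cdh11 transcripts were present in every library, and the libraries labelled knockout did not hold fewer of them. Cdh11 (ENSMUSG00000031673, mm10 chromosome 8, 102632095 to 102785642, minus strand) had 479, 338 and 932 counts in the wild-type-labelled libraries and 953, 684, 1006 and 876 in the knockout-labelled ones. These are 6.79, 4.52 and 10.77 CPM against 11.26, 9.56, 11.64 and 10.98 CPM. The log2 fold change of knockout over wild type was 0.56 (SE 0.26, adjusted p = 0.14, edgeR). Its 95% confidence interval, from -0.10 to 1.21, was computed from this SE and a t distribution with 5 degrees of freedom, apart from edgeR's test. Without wild-type-labelled replicate 3 the log2 fold change was 0.93 (adjusted p = 0.0043, edgeR). Counts per gene do not show which part of the gene the reads cover, and the allele is not described in the sources used here. Because the target goes against the labels, every direction given here is between libraries labelled knockout and libraries labelled wild type.

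**Figure D1:**
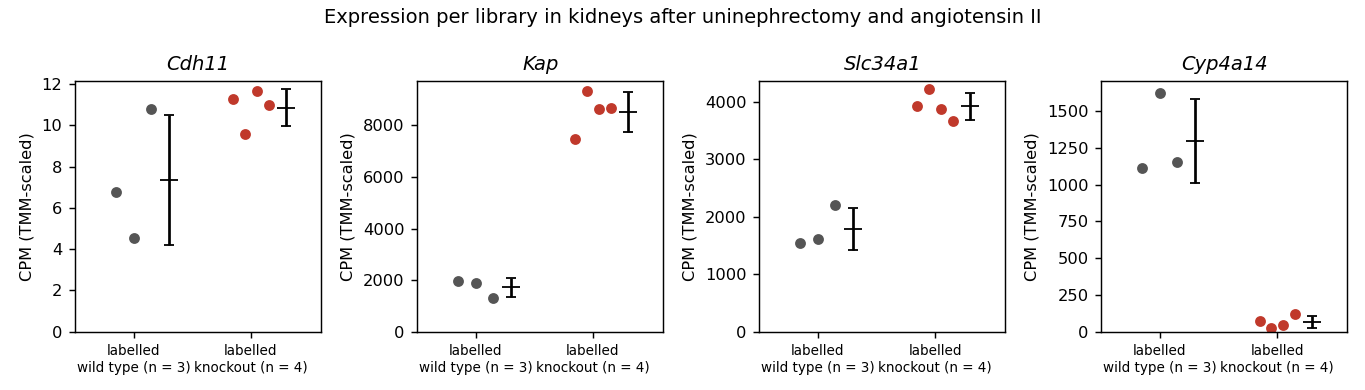
Expression of Cdh11, Kap, Slc34a1 and Cyp4a14 in CPM (vertical axes) in each library (points), by labelled genotype, with the mean and SD of each group beside the points (n = 3 and 4). Cdh11 values overlap between the groups, and those of the other genes do not.

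Kidney expression separated the labelled genotypes widely. Of 17964 genes tested, 5327 (29.7%) were called, 3012 higher and 2315 lower in the knockout-labelled libraries, and 896 changed by at least 1 on the log2 scale (620 higher, 276 lower). The groups did not overlap in 38.5% of the tested genes, where chance gives 5.7%. The first principal component held 48.7% of the variance and parted the genotypes, and Spearman correlations were 0.9892 to 0.9945 within a genotype and 0.9778 to 0.9849 between genotypes. Summed CPM of the Y-linked genes Uty, Kdm5d, Ddx3y and Eif2s3y was 64.7 in wild-type-labelled replicate 3 and 110.8 to 144.9 in the other 6, and 5300 genes were called without that library. These Y-linked genes were chosen after their values were seen.

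Transporters of the proximal tubule were among the largest rises. Slc22a7, an organic anion transporter, rose from 5.91 ± 2.35 CPM (SD, n = 3) to 107.6 ± 11.5 CPM (SD, n = 4), or 18.1-fold (adjusted p = 9.05e-05, edgeR). Slc7a13, an amino acid transporter, rose 14.8-fold, the organic anion transporter Slco1a1 12.7-fold and the acyl-CoA synthetase Acsm3 9.72-fold. Without wild-type-labelled replicate 1 the log2 fold change of Slc7a13 was 4.51 against 3.892. Col6a6, a collagen VI chain, rose by a log2 fold change of 4.71 from 0.069 CPM, and Kcng1, Mfsd2a, Angptl7, Tmprss9 and Pde6a rose by 3.33, 3.26, 3.21, 3.15 and 3.00, with 4.047 for Kcng1 without wild-type-labelled replicate 3. The largest rise among genes with a mean of at least 1 CPM was that of Gm6300 (7.45), annotated as a pseudogene. Serpina1d, of a cluster of near-identical protease inhibitor genes, rose by 6.74 (SE 1.77, adjusted p = 0.0351), a call lost in 9 of 18 alternatives. It stood at 84.57, 28.39 and 53.26 CPM in knockout-labelled replicates 1 to 3 but at 0.64 CPM in replicate 4, against 0.44, 0.09 and 0.61 CPM in the wild-type-labelled libraries. The call was lost without each library except knockout-labelled replicate 4 (adjusted p of up to 0.123), and the log2 fold change was 6.136 without knockout-labelled replicate 1. The division of reads between these genes and their copies is uncertain.

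Androgen-dependent kidney genes were higher as a group in the knockout-labelled libraries. Of 12 members, 11 rose and 0 fell (11 and 0 adjusted over the list alone), with a median log2 fold change of 1.86. Kap, the androgen-regulated kidney protein, rose from 1718 ± 365 CPM (SD, n = 3) to 8519 ± 773 CPM (SD, n = 4), and Odc1, the ornithine decarboxylase of polyamine synthesis, rose 6.88-fold (adjusted p = 4.46e-05, edgeR). Cyp2j13 and Gusb rose 4.81-fold and 2.33-fold. The list had a camera adjusted p = 6.44e-10, and adjusted p = 0.231 with an estimated correlation. None of the 17 lists that camera called was called with an estimated correlation, where 5 had an unadjusted p under 0.05. Fry, which asks whether the genes of a list move 1 way without comparing them with other genes, called 14 of these 17 and 2 others.

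Proximal tubule markers rose in 14 of 22 and fell in 1 (14 and 1 adjusted over the list alone). The phosphate transporter Slc34a1 rose from 1787 ± 365 CPM (SD, n = 3) to 3925 ± 231 CPM (SD, n = 4), and the fatty acid transporter Slc27a2 rose 1.48-fold. The median log2 fold change was 0.55 (camera adjusted p = 3.99e-05, and adjusted p = 0.355 with an estimated correlation). Kap is in this list and in the androgen list.

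The largest fall among genes with a mean of at least 1 CPM was that of Greb1, a hormone-responsive gene. It fell from 22.5 ± 5.33 CPM (SD, n = 3) to 0.516 ± 0.188 CPM (SD, n = 4), a 44.0-fold difference (adjusted p = 1.49e-05, edgeR). Cyp4a14, a fatty acid hydroxylase, was 19.5-fold lower. The glucuronosyltransferases Ugt1a2, Ugt1a9 and Ugt1a10 were 29.8-fold, 18.1-fold and 14.1-fold lower, and the glutathione transferases Gsta1 and Gsta2 10.9-fold and 7.43-fold lower. Ugt1a genes share exons and the Gsta genes are near-identical, so their separate values are uncertain. For Ugt1a9 the log2 fold change was -4.181, and -5.616 without knockout-labelled replicate 3. Marc1, the carbonyl reductase Cbr3 and the nuclear receptor gene Nr4a3 were 12.6-fold, 9.95-fold and 8.58-fold lower.

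Of 15 oxidative stress genes 7 fell and 3 rose (7 and 3 adjusted over the list alone), with Nqo1 2.91-fold, Srxn1 2.21-fold and Gsta4 1.99-fold lower in the knockout-labelled libraries. The median log2 fold change was -0.52 (camera adjusted p = 0.0104, and adjusted p = 0.231 with an estimated correlation). The number rising was 1 without wild-type-labelled replicate 2 or knockout-labelled replicate 4 and 2 without each other library. Fatty acid oxidation genes were not called as a list (camera adjusted p = 0.184), with 3 members higher and 6 lower of 20 (3 and 7 adjusted over the list alone), and 5 higher and 4 lower without wild-type-labelled replicate 2. Among them Cyp4a10 was 4.65-fold and Acaa2 1.63-fold lower, while Acadm and Acads were 1.77-fold and 1.37-fold higher.

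In the oxidative phosphorylation list 18 of 20 genes rose and 0 fell (19 and 0 adjusted over the list alone), with a median log2 fold change of 0.29. Ndufa4 rose 1.38-fold, Uqcrfs1 1.37-fold, Ndufa1 1.35-fold and Sdhb 1.31-fold. The camera adjusted p was 6e-08, and adjusted p = 0.231 with an estimated correlation, and 10 members were called without wild-type-labelled replicate 1. Proximal tubule markers rose in the same libraries (median log2 fold change 0.55) and camera called the endothelial and principal cell lists lower, so a difference in cell make-up was not separated from a change within cells.

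Cholesterol synthesis and cell cycle genes were also higher. For cholesterol synthesis 9 of 15 genes rose and 0 fell (9 and 0 adjusted over the list alone), among them Idi1 (3.46-fold), Cyp51 (2.97-fold), Mvd (2.13-fold) and Dhcr7 (1.61-fold), with camera adjusted p = 7.9e-05 and adjusted p = 0.355 with an estimated correlation. In the proliferation list 15 of 16 genes rose and 0 fell (15 and 0 adjusted over the list alone), with a median log2 fold change of 1.40. The replication gene Mcm5 rose from 2.22 ± 0.575 CPM (SD, n = 3) to 4.61 ± 0.343 CPM (SD, n = 4), and the mitotic genes Aurkb, Bub1 and Ccnb2 rose 3.99-fold, 4.16-fold and 2.62-fold from under 1 CPM. Camera gave an adjusted p = 6.73e-06 for proliferation, and adjusted p = 0.355 with an estimated correlation.

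Interstitial matrix genes rose in 7 of 26 and fell in 1 (8 and 2 adjusted over the list alone), with 18 not called. Col3a1, a fibrillar collagen, rose 2.64-fold (28.4 ± 13.5 CPM, SD, n = 3, to 74.9 ± 10.1 CPM, SD, n = 4), Col15a1 2.21-fold and Mgp 1.90-fold. The call for Col3a1 was lost without wild-type-labelled replicate 1 or knockout-labelled replicate 1, 2 or 3 (adjusted p of up to 0.0736). Camera gave an adjusted p = 0.0276, adjusted p = 0.722 with an estimated correlation, and fry an adjusted p = 0.226. The call was lost without wild-type-labelled replicate 2 (adjusted p = 0.101) and without knockout-labelled replicate 1 (adjusted p = 0.122). The number of genes that rose was 2 without wild-type-labelled replicate 1 or knockout-labelled replicate 3, 3 and 4 without knockout-labelled replicates 1 and 4, and 11 without wild-type-labelled replicate 3. The number that fell was 0 without wild-type-labelled replicate 1 or knockout-labelled replicate 3 or 4, and 2 without knockout-labelled replicate 1. Without the low-count filter 2 genes of this list rose and 0 fell, and with 1 surrogate variable 13 rose and 2 fell.

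TGF-beta response genes, which accompany fibrosis, fell in 6 of 14 with 0 rising (7 and 0 adjusted over the list alone). Ccn1 was 2.65-fold, Thbs1 1.83-fold, Tgfb2 1.62-fold and Smad7 1.39-fold lower. Smad7 encodes an inhibitor of the pathway. Camera gave an adjusted p = 0.00501, and adjusted p = 0.355 with an estimated correlation.

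Other adhesion and matrix lists were not called. Of the genes named below, Cdh16, Cdh3 and Mmp2 lie within 10 Mb of Cdh11. Cadherins and catenins had 2 members higher and 4 lower of 12 (2 and 6 adjusted over the list alone, camera adjusted p = 0.297), with the kidney cadherin Cdh16 1.42-fold higher, and Cdh6 1.70-fold and Cdh3 1.48-fold lower. Basement membrane genes had 4 higher and 4 lower of 16 (4 and 4 adjusted over the list alone, camera adjusted p = 0.896), with the glomerular collagens Col4a3, Col4a4 and Col4a5 1.56-fold, 1.31-fold and 1.23-fold higher and the laminin Lamb1 1.29-fold lower. Matrix proteases and inhibitors had 3 higher and 3 lower of 16 (4 and 4 adjusted over the list alone, camera adjusted p = 0.898), among them Mmp2 (1.79-fold higher) and Timp3 (1.34-fold higher). Markers of fibroblasts, pericytes and smooth muscle had 1 higher and 4 lower of 16 (1 and 4 adjusted over the list alone, camera adjusted p = 0.59), with Mcam 1.63-fold and Pdgfrb 1.27-fold lower. For the fibroblast list the median log2 fold change was -0.01, the mean 0.02 and the camera direction down, and for basement membrane and proteases camera pointed down and fry up. The number of genes that fell dropped to 2 for cadherins without wild-type-labelled replicate 1 or 2, for basement membrane without wild-type-labelled replicate 1 or 3 or knockout-labelled replicate 2 or 4, and for fibroblasts without wild-type-labelled replicate 1 or 3 or knockout-labelled replicate 3. For proteases it was 0 without wild-type-labelled replicate 1 or knockout-labelled replicate 2, 3 or 4, 1 without wild-type-labelled replicate 3 and 5 without knockout-labelled replicate 1. The number that rose was 1 for cadherins without wild-type-labelled replicate 1, and 0 for fibroblasts without each library except knockout-labelled replicate 1. Camera called the fibroblast list lower without wild-type-labelled replicate 2 (adjusted p = 0.046).

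Tubular injury markers fell in 5 of 16 and rose in 1 (6 and 1 adjusted over the list alone). Gdf15, a stress-induced cytokine, fell from 20.7 ± 5.51 CPM (SD, n = 3) to 5.85 ± 1.69 CPM (SD, n = 4), ceruloplasmin (Cp) was 3.03-fold and keratin Krt18 2.91-fold lower, and the integrin Itgb6 was 2.15-fold higher. Havcr1, the KIM-1 gene, singled out after its values were seen, did not pass the test (log2 fold change 0.25, adjusted p = 0.835). Camera gave an adjusted p = 0.0151, adjusted p = 0.355 with an estimated correlation, and 0.0583 without wild-type-labelled replicate 3. Without wild-type-labelled replicate 2, 9 members fell.

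Unfolded protein response genes fell together, 10 of 14 with 0 rising (11 and 0 adjusted over the list alone) and a median log2 fold change of -0.66. Hspa5, the chaperone BiP, fell from 676 ± 63.7 CPM (SD, n = 3) to 352 ± 48.5 CPM (SD, n = 4), and the stress transcription factors Atf3 and Ddit3 were 6.69-fold and 2.21-fold lower, with Dnajb9 1.90-fold lower. Camera gave an adjusted p = 2.51e-06, and adjusted p = 0.231 with an estimated correlation. Immediate-early and heat shock genes, which also respond to tissue handling, fell in 7 of 14 with 0 rising (9 falling adjusted over the list alone), among them Fos (8.59-fold), Egr1 (3.66-fold) and Hsph1 (1.49-fold), with camera adjusted p = 3.99e-05 and adjusted p = 0.231 with an estimated correlation. Their falling members numbered 4 without wild-type-labelled replicate 3 or knockout-labelled replicate 3.

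Principal cell markers fell in 5 of 10 with 0 rising (5 and 0 adjusted over the list alone), including the sodium channel subunits Scnn1g (1.65-fold) and Scnn1a (log2 fold change -0.59), and the vasopressin receptor Avpr2 (log2 fold change -0.59). Thick ascending limb markers fell in 3 of 9 and rose in 1 (4 and 1 adjusted over the list alone), with the potassium channel Kcnj1 1.59-fold lower and Cldn10 1.25-fold higher, a rise not called without wild-type-labelled replicate 1 or 2 or knockout-labelled replicate 2 (adjusted p of up to 0.0615). Intercalated cell markers fell in 3 of 10 with 0 rising (4 and 0 adjusted over the list alone), among them Slc4a9 (1.57-fold) and Atp6v1g3 (1.47-fold), calls lost in 9 and 5 of 18 alternatives. The number falling in this list was 0 without wild-type-labelled replicate 1 or knockout-labelled replicate 1 or 3, 1 without wild-type-labelled replicate 2 or knockout-labelled replicate 2 or 4, and 6 without wild-type-labelled replicate 3. Camera gave adjusted p = 0.00948, 0.0179 and 0.0174 for these lists, and adjusted p = 0.355, 0.355 and 0.431 with an estimated correlation. The thick ascending limb call was lost without wild-type-labelled replicate 1 (adjusted p = 0.0511) and the intercalated cell call without replicate 2 (adjusted p = 0.065) and with fry (adjusted p = 0.118), and 3 principal cell markers fell without knockout-labelled replicate 2. Distal convoluted tubule markers were not called as a list (camera adjusted p = 0.173), with 4 of 10 lower and 0 higher (5 and 2 adjusted over the list alone), among them the sodium-chloride cotransporter Slc12a3 (1.71-fold). In this list 1 member fell without wild-type-labelled replicate 2 or knockout-labelled replicate 3, 2 fell without knockout-labelled replicate 4, and 2 fell and 3 rose without knockout-labelled replicate 1.

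Podocyte markers fell in 6 of 12 with 0 rising (6 and 0 adjusted over the list alone), with Wt1 1.79-fold, Synpo 1.54-fold, Podxl 1.41-fold and Ptpro 1.39-fold lower. Endothelial markers fell in 7 of 14 with 0 rising (7 and 0 adjusted over the list alone), with the VEGF receptor Flt1 falling from 118 ± 12.3 CPM (SD, n = 3) to 73.6 ± 5.93 CPM (SD, n = 4), and Pecam1 1.29-fold and Ptprb 1.28-fold lower. Camera gave adjusted p = 0.0158 for podocytes and 0.000306 for endothelium, and adjusted p = 0.451 and 0.355 with an estimated correlation. The podocyte call was lost without wild-type-labelled replicate 1 (adjusted p = 0.0562) and with fry (adjusted p = 0.0525), and 3 endothelial markers fell without that library and 4 without knockout-labelled replicate 4.

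Few immune genes passed the test, and most that did were scarce neutrophil and cytokine transcripts. Of 5 tested neutrophil markers 4 fell (5 adjusted over the list alone), with S100a9 falling from 1.19 ± 0.605 CPM (SD, n = 3) to 0.278 ± 0.211 CPM (SD, n = 4), and Retnlg under 1 CPM in both groups (camera adjusted p = 0.00501, and adjusted p = 0.355 with an estimated correlation). The S100a9 call was lost without wild-type-labelled replicate 1 or 3 or knockout-labelled replicate 2 or 3 (adjusted p of up to 0.0665), and its log2 fold change was -2.109, and -2.753 without knockout-labelled replicate 4. The number falling was 2 without wild-type-labelled replicate 1 or knockout-labelled replicate 2 and 1 without wild-type-labelled replicate 3. Chemokines and cytokines had 4 of 14 lower and 1 higher (5 and 1 adjusted over the list alone, camera adjusted p = 0.0639), with Il1b 3.09-fold, Ccl2 2.94-fold and Cxcl1 2.70-fold lower and Il34 1.38-fold higher. Macrophage markers had 1 higher, Csf1r at 1.80-fold, and 1 lower, Ms4a7, of 16 (0 and 0 adjusted over the list alone, camera adjusted p = 0.34). The Csf1r and Ms4a7 calls were lost in 5 and 9 of 18 alternatives, with 0 higher and 0 lower without wild-type-labelled replicate 1 or knockout-labelled replicate 1, 3 or 4, and 1 higher and 0 lower without wild-type-labelled replicate 3 or knockout-labelled replicate 2. No member of the T and NK cell list (13 tested, camera adjusted p = 0.866), the B and plasma cell list (11 tested, 0.59) or the interferon response list (16 tested, 0.0872) passed the edgeR test, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 edgeR counted 0, 1 and 4 members of these lists, while DESeq2 called 0, 1 and 4 and limma-voom 0, 1 and 0 after adjustment. Without wild-type-labelled replicate 2, camera called macrophages (adjusted p = 0.000864), interferon response (2.57e-05) and chemokines (0.00245) lower, and 7, 9 and 7 of their genes fell, with 1 of the T and NK cell list. Without wild-type-labelled replicate 3, 1 B and plasma cell gene and 1 interferon response gene rose. Interferon response was also called lower without knockout-labelled replicate 3 (0.0424) and with 1 surrogate variable (0.0227), and chemokines without wild-type-labelled replicate 1 (0.0399), with 1 surrogate variable (0.0285) and without the low-count filter (0.00757). Without wild-type-labelled replicate 3 the mean log2 fold change of macrophage markers turned from -0.29 to 0.07. Complement and acute phase genes were not called (camera adjusted p = 0.3), with 2 lower and 1 higher of 12 (2 and 1 adjusted over the list alone), including C3, which fell 5.06-fold. The counts were 1 lower and 0 higher without wild-type-labelled replicate 1 or knockout-labelled replicate 2, and 1 and 1 without knockout-labelled replicate 1 or 4. Without wild-type-labelled replicate 3, 4 members rose and 1 fell, and the mean log2 fold change turned from -0.65 to 0.21.

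Components of the renin-angiotensin system were higher in 5 of 11 and lower in 0 (6 and 1 adjusted over the list alone). Ace rose from 108 ± 5.68 CPM (SD, n = 3) to 238 ± 17.8 CPM (SD, n = 4) and Mas1 rose 9.22-fold from 0.079 CPM. The list was not called by camera (adjusted p = 0.0836) but was by fry (adjusted p = 0.00174) and by camera without wild-type-labelled replicate 1 (adjusted p = 0.0399), and 3 members rose without replicate 2. Without wild-type-labelled replicate 3, 2 members fell, and without knockout-labelled replicate 4, 1 fell. Clock genes were not called by camera (adjusted p = 0.0872) but were by fry (adjusted p = 0.0176, direction down), with 1 higher and 2 lower of 14 (0 and 1 adjusted over the list alone), among them Per2 at 1.92-fold lower. The counts were 2 higher and 5 lower without knockout-labelled replicate 1, 0 and 2 without replicate 4, and 0 and 1 without each other library. Red blood cell genes had 1 higher and 1 lower of 8 (1 and 1 adjusted over the list alone, camera adjusted p = 0.898). These counts were 0 and 0 without wild-type-labelled replicate 1 or 3 or knockout-labelled replicate 2 or 3, 0 and 1 without wild-type-labelled replicate 2, and 1 and 0 without knockout-labelled replicate 1. Of other tissues a kidney sample can carry, 3 adipocyte markers were tested, of which Lipe rose 1.53-fold (1 rise adjusted over the list alone), and of 4 adrenal cortex markers 0 passed the test (0 adjusted over the list alone, at an unadjusted p under 0.05 in edgeR, or by DESeq2 or limma-voom), too few members for camera.

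**Figure D2:**
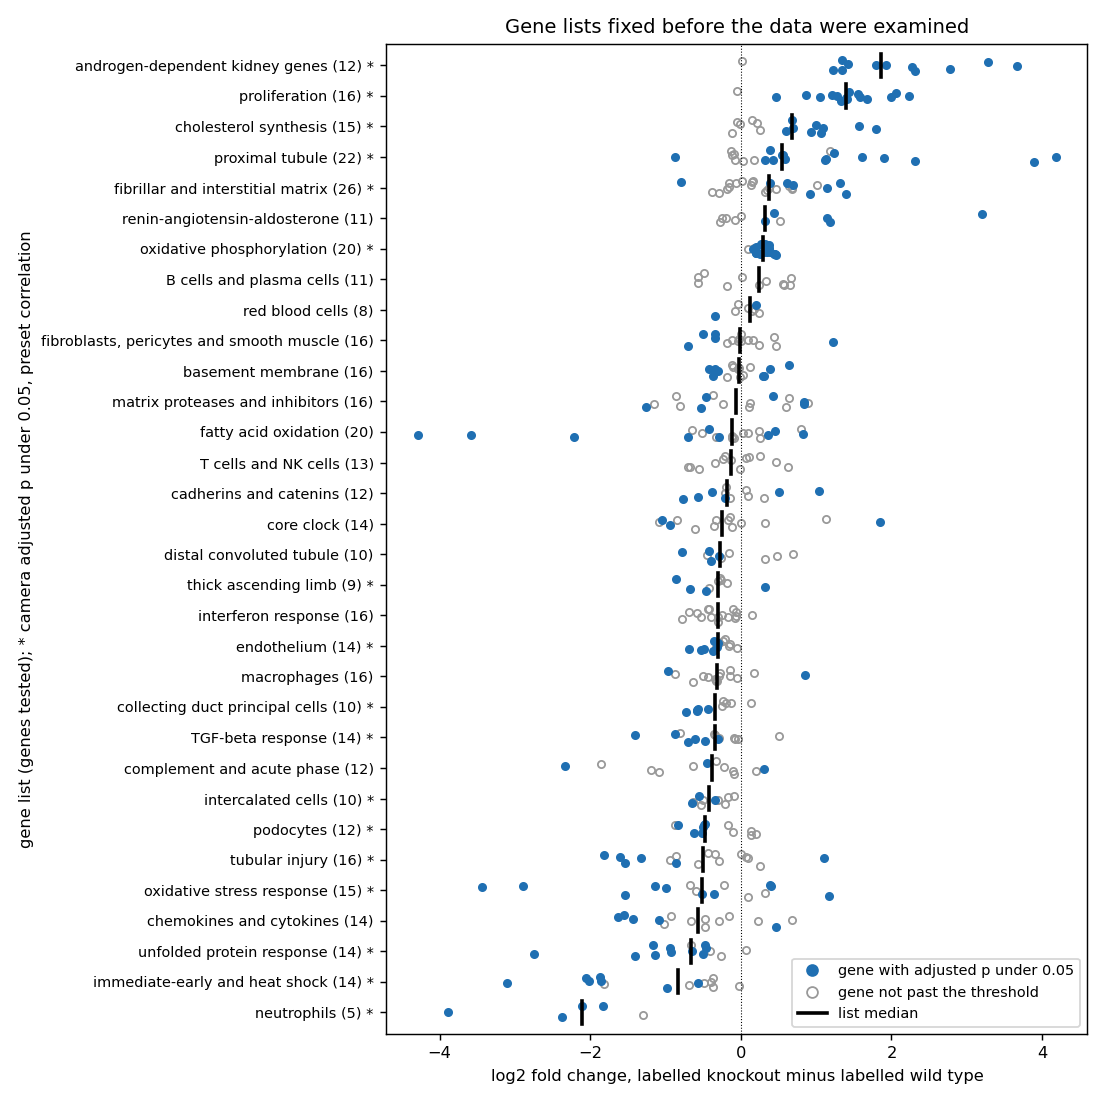
Log2 fold change (horizontal axis, knockout-labelled minus wild-type-labelled) of each tested gene in the 32 lists tested by camera (rows, with genes tested). Filled points passed the edgeR test, bars are list medians, and stars mark the 17 lists called with the preset correlation, 6 higher and 11 lower.

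Genes around Cdh11 were not called more often than genes elsewhere beyond counting error. The Fisher's exact test used here treats neighbouring genes of the same mice as independent. It does not measure the spread between animals. Within 10 Mb of Cdh11, 64 of 197 genes were called (32.5%), against 5263 of 17766 elsewhere (29.6%), an odds ratio of 1.14 with a 95% confidence interval from 0.833 to 1.55 (p = 0.389, 2-sided Fisher's exact test). The carboxylesterases Ces1f and Ces2h rose 2.64-fold and 3.49-fold, the lactate dehydrogenase Ldhd rose 2.27-fold, and Nqo1 fell 2.91-fold. Carboxylesterase genes of this cluster are similar in sequence, so reads of Ces1f and Ces2h are shared with their neighbours to an unknown extent. Cdh16, Cdh3, Mmp2, Slc12a3 and Il34, named above with their lists, also lie in this window. On a mixed background, alleles linked to Cdh11 can differ between the genotypes. For single genes of the window such a difference was not separated from another effect of genotype.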

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

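The tests of the Cdh11, androgen and Y-linked patterns were chosen after the results were seen, except that of the X-linked copies, and the test for female tissue in wild-type-labelled replicate 3 was widened to include those copies after its values were known. The split of libraries was planned.

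The count of 5327 called genes was compared with other groupings of the 7 libraries. Of the 35 splits into 3 and 4, 1 gave as many genes, the genotype split itself, and the highest of the others gave 16. The count thus follows the labelled split. Each other split mixes the labelled groups, so low counts were to be awaited there. The comparison cannot tell genotype from another property shared by the mice of a group.

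Cdh11 was not lower in the libraries labelled knockout. An exchange of labels between the groups would need the wild-type-labelled libraries to lack Cdh11, and the lowest of them held 4.52 CPM, but a line whose allele keeps a transcript would hold reads in either group. A counted transcript of another length could shift the gene-specific factor behind the deposited normalized values. The factor of Cdh11 was lower in knockout-labelled libraries by a log2 difference of -0.394, a difference that 1.58% of genes match or exceed, yet the factors of the groups overlapped (0.867 to 1.459 and 0.876 to 0.902). Exchanged labels and an allele that leaves a counted transcript cannot be told apart here, because the allele is not described and counts per gene do not show which exons were read, and genotype stays open as the origin of the other differences.

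Androgen-dependent genes were higher in the knockout-labelled libraries, and in wild-type-labelled replicates 1 to 3 their median was 0.283, 0.28 and 0.249 of the knockout-labelled mean. Female tissue would lower Y-linked genes to about the same share, but these stood at 1.251, 1.145 and, at the lowest, 0.559. A smaller share of proximal tubule would lower its other markers equally if all its cells were lost alike. The androgen-dependent median exceeded theirs by 1.32 on the log2 scale (1.86 against 0.54, permutation p = 0.00946, 2-sided). This p treats genes of the same mice as independent and does not measure the spread between animals. The androgen list was also taken up after its rise was seen. The larger difference in its genes therefore does not exclude a smaller share of proximal tubule. A difference in androgen exposure between the mice, with genotype or with another property of the animals, may lie behind the androgen-dependent rise. This hypothesis was not tested, since hormone levels were not analysed here.

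Y-linked genes were low in wild-type-labelled replicate 3, at 0.47 (Uty), 0.52 (Kdm5d), 0.59 (Ddx3y) and 0.51 (Eif2s3y) of the mean of the other 6 libraries. Reads moved to the X-linked copies would raise those by about the missing 58.8 CPM, but their sum was lower than the mean of the others (a difference of -37.0 CPM). Female tissue in the sample would raise Xist and the X-linked copies, but Xist was 0.98 of the highest of the other 6 and the copies, at 349.8 CPM, were below their range of 360.4 to 421.4. Xist was 0.92 CPM there and 0.94 CPM in wild-type-labelled replicate 2, against 0.13 to 0.29 CPM in the other 5, and these values have no tested explanation. No other explanation was tested for this library, without which 5300 genes were called, including 84.6% of those called with it.

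Among the 4 knockout-labelled libraries, 10 of 145 values tested stood apart from the other 3 by Dixon's criterion, where chance gives 7.2. Replicate 1 stood apart for Dhcr7 (17.63 CPM, others 14.53 to 15.05) and Nr4a3 (1.82 CPM, others 0.53 to 0.73). Replicate 2 stood apart for Greb1 (0.8 CPM, others 0.4 to 0.44), Krt18 (10.47 CPM, others 13.1 to 13.48), Lck (0.46 CPM, others 0.79 to 0.8) and Timp3 (2056.42 CPM, others 1581.01 to 1629.65). Replicate 3 stood apart for Jchain (16.13 CPM, others 11.65 to 12.3), Scnn1g (35.29 CPM, others 44.2 to 45.27) and Uqcrfs1 (224.82 CPM, others 208.28 to 210.42). Replicate 4 stood apart for S100a8 (0.35 CPM, others 0.05 to 0.08).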

How the results depend on the processing

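The fit with the deposited gene-specific factors and the fit on protein-coding genes were chosen after seeing the data. No paired analysis was possible because the labels give the libraries no shared replicate numbers. The number of called genes ranged from 4651 (deposited factors) to 6005 (DESeq2) over other tools, scalings and filters at the same threshold, and from 3804 (without wild-type-labelled replicate 1) to 5300 (without wild-type-labelled replicate 3) when a library was left out. Requiring a log2 fold change of at least 1 left 896 genes, 620 higher and 276 lower, by construction of a stricter threshold. With the deposited factors 80.7% of the main calls were called again, and 12 had the other sign. The median log2 fold change of all genes was -0.014, and -0.027 at the lowest under other scalings. The log2 fold change of Cdh11 was 0.07934 (adjusted p = 0.888) with the deposited factors and 0.2436 (adjusted p = 0.646) with limma-trend on the deposited values. Both fits use the deposited factor of Cdh11, whose log2 difference of knockout-labelled minus wild-type-labelled libraries (-0.394) lowers the fold change. Cdh11 was called higher with limma-voom (log2 fold change 0.7473) and with 1 surrogate variable (0.6225). Without single libraries its log2 fold change ranged from 0.3043 to 0.9334, where only the omission of wild-type-labelled replicate 3 gave a call. The cause of these other shifts was not tested. With an estimated correlation camera called 0 of the 17 lists, and fry called 14 of them and 2 others. The estimated correlations of the 17 lists ran from 0.01 (oxidative stress response) to 0.758 (neutrophils), against the preset 0.01. A correlation above the preset makes camera's p larger, so the small p-values at the preset rest on that setting. The oxidative stress list was lost at 0.01 too (camera unadjusted p = 0.00389 preset, 0.0344 estimated), so the correlation does not account for every loss. Near Cdh11 no alternative gave a call. Depth limits the transcripts under 1 CPM, such as most neutrophil markers, which the filter at 1 CPM removes.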

Other observations

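Other genes, chosen after their values were seen, also differed between the labelled genotypes. Cbr1, a carbonyl reductase beside Cbr3, had the smallest p of all genes and fell from 120 ± 14.8 CPM (SD, n = 3) to 19.4 ± 1.09 CPM (SD, n = 4), with adjusted p = 2.78e-06 in edgeR. The export pump Abcc3 was 5.39-fold lower and Ugt1a1, which shares exons with its neighbours, 5.51-fold lower in the knockout-labelled libraries. The prolactin receptor Prlr was 5.77-fold and the amino acid transporter Slc7a12 7.07-fold lower. Srd5a1, which converts testosterone to dihydrotestosterone, rose 1.66-fold.

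The make-up of the libraries differed between the groups. Protein-coding genes took 61.92%, 62.65% and 66.97% of the counts in wild-type-labelled replicates 1 to 3 and 68.49% to 70.17% in the knockout-labelled libraries, and the 10 most abundant genes took 35.5% ± 2.73 (SD, n = 3) against 29.8% ± 0.75 (SD, n = 4). With protein-coding genes alone, 5094 genes were called.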
